A study of Mus musculus with 8 samples.

How the data were processed

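Ear skin of adult mice was profiled on 8 arrays, 4 from mice with the corneodesmosin gene Cdsn inactivated in the epidermis (KO) and 4 from control mice (WT). Both genotypes carried a tamoxifen-inducible Cre recombinase driven by a KRT14 promoter, which is active in basal keratinocytes, and both received 4-hydroxytamoxifen on the ears, so the drug and the recombinase were common to the groups. KO mice had 2 floxed Cdsn alleles and WT mice had none. Each array came from a different mouse, per the labels. Tissue stood in RNA preservative for up to 4 weeks, and 9 µg of total RNA per sample was labelled, per the labels' protocols.

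The authors deposited log2 expression values for 33793 probe sets on 8 arrays, made with RMA per the submitters' processing notes, whose version is not given in the sources used here. RMA corrects the background of each array, normalizes between arrays and summarises the probes of a probe set; which of its options were used, and by what rule these probe sets were kept, is likewise not given in the sources used here. The array type is Affymetrix Gene Mouse 2.0 ST per the file headers. The authors also deposited a table of 3411 probe sets with a log2 fold change, a linear fold ratio, a p-value and an adjusted p-value for KO against WT, together with gene symbols, accessions, chromosomes and a cross-hybridisation class. Its p-values and those of the fit described next differed by a ratio of at most 1 plus 6.68e-08, and its entries were the 3411 probe sets with adjusted p under 0.05 and a log2 fold change of at least 0.5 either way. Class 3 in that table marks probe sets whose probes also match other transcripts; 674 of the 3411 were of that class, and named genes of that class are pointed out.

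Values were used as deposited. A linear model was fitted to all 33793 probe sets with limma 3.58.1 in R 4.3.3, KO minus WT, with empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over all probe sets. A probe set was called at adjusted p under 0.05. For Cdsn an exact two-sided permutation test of the 8 values was added. The number of arrays limits the precision: in 5 simulated data sets of 33793 probe sets, 77.1% of changes of 1 log2 unit and 95.2% of changes of 2 log2 units were recovered, and 4.11% of calls were false. In these, 200 probe sets changed per size, and the noise was normal and independent between probe sets and arrays. The real arrays share variation that this leaves out, so the rates of the real comparison can differ. No column lacked a sample.

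Gene names came from the authors' deposited table alone, so all other probe sets stay unnamed here and names exist only for probe sets that met the authors' criteria. Of the 3411 probe sets, 3220 had a symbol; 2660 were matched to RefSeq genes of GRCm38.p6, 1947 by accession, 675 by symbol and 38 by an older symbol, and 560 kept the table's symbol. Where a gene had several probe sets, the one with the highest mean over the 8 arrays was used, which gave 3022 genes, 2253 higher and 769 lower. A further 1017 called probe sets had smaller changes and no name. Because of this, 4 parts of the plan could not be carried out: fitting 1 probe set per gene over all genes, averaging a gene's probe sets, the camera and fry tests of gene lists, and counts adjusted over the list alone. Counts of calls are therefore counts of probe sets.

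For 38 gene lists fixed before the data were examined, the test used in place of camera was chosen after seeing the data. It is a one-sided Fisher's exact test of the share of a list's protein-coding members found in the table as higher, or as lower, against the share among all other protein-coding genes of the reference, 21900 in all. The 37 lists tested in both directions made 74 tests, adjusted together with Benjamini-Hochberg; the sex-linked list was left out. The test treats genes as independent and takes every reference gene as present on the array, and a member missing from the table either missed the criteria or had no probe set tested. The members of the other lists served as a second background. In 20 simulated runs on 21900 genes, a planted list with 6 of 18 members called was found 20 times, and 0 of the 36 random lists per run were called. The planted count was the same in every run, and members were drawn independently of one another. The runs therefore check the calculation, and give neither power nor an error rate for lists of co-regulated genes. Software was Python 3.11.15 with scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and statsmodels 0.14.6; figures used matplotlib 3.10.9.

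Genes are named by a rule set before the data were examined: Cdsn, the 10 largest rises and 10 largest falls among called genes whose 4 KO values all lie to one side of the 4 WT values, up to 4 called members of each list that passed or that holds at least 3 called members, and up to 2 of any other list. This took 87 genes. A few results that the rule would name are not reported here. Genes outside the rule are marked as chosen after their values were seen. In addition, 3 lists of oxygen-regulated, NF-kB feedback and muscle genes were drawn up after the values were seen and partly from the genes that had changed; testing them against the same data was circular, so those tests are not reported and values alone are given.

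Alternatives planned were quantile normalization, median centring, leaving out probe sets with a mean under the median of 5.50, array weights, a trended robust prior, no moderation, the replicate number as a block, each array left out in turn, adjusted p thresholds of 0.01 and 0.1, and a fold minimum of 2. In these alternatives a list member counted if it was in the table, still called and still changed by 0.5 log2 units in the same direction, so members could be lost and none outside the table gained. The labels name no labelling or scan batch, and none was tested.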

Results

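The comparison asks how ear skin changes when corneodesmosin is removed from the epidermis of adult mice. Corneodesmosin is a secreted glycoprotein of the corneodesmosomes, the junctions that hold the cells of the outermost skin layers together. Ear skin came from 4 KO and 4 WT mice, 7 to 12 weeks old when treated, which had 100 µg of 4-hydroxytamoxifen applied to each ear daily for up to 15 days. Values are RMA-processed log2 values of 33793 probe sets. Array medians were 5.52 to 5.59 in KO and 5.43 to 5.49 in WT, and the first principal component, with 50.4% of the variance, ran from KO replicate 1 at -75.3 to WT replicate 3 at 50.5. WT replicate 1 lay at 2.60 on it, beside KO replicates 3 and 4 at -4.47 and -6.84 and far from the other WT arrays at 43.5 to 50.5.

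Cdsn itself fell to 19.3% of its WT level. Its mean log2 value was 9.63 ± 0.60 in KO and 12.00 ± 0.16 in WT (SD, n = 4 each), a log2 difference of -2.37 (SE 0.26, limma adjusted p = 0.00203; exact permutation p = 0.0286, the smallest that 8 arrays allow). The KO arrays read 10.31, 8.89, 9.82 and 9.49, and the WT arrays read 12.05, 11.76, 12.13 and 12.06, so no KO array reached the WT range. A single probe set of 24 probes measured Cdsn, on chromosome 17 per the authors' deposited table. Whether its probes lie in the deleted part of the gene was not analysed here. Ear skin also holds cells in which the recombinase is not active.

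**Figure D1:**
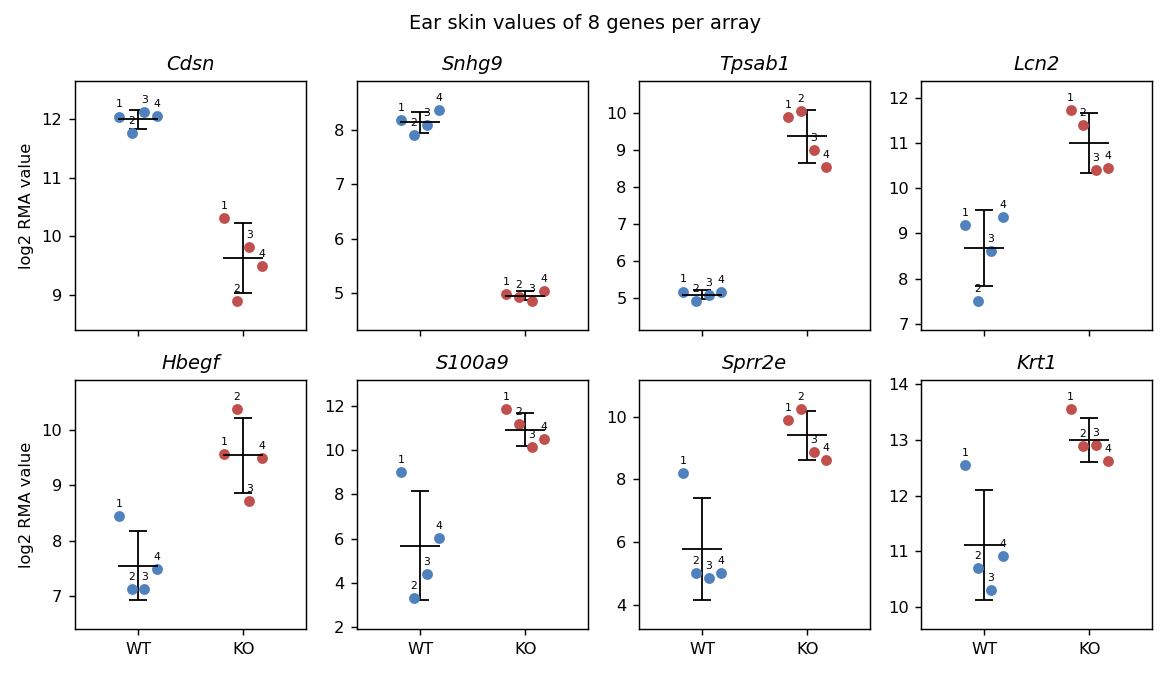
Log2 RMA values of 8 genes in each array of ear skin, WT in blue and KO in red, with replicate numbers beside the points; long bars are means and whiskers are SD (n = 4 per group), and each panel has its own vertical axis, which does not start at 0. Cdsn lies between 8.89 and 10.31 in KO and between 11.76 and 12.13 in WT, while S100a9 in WT replicate 1, at 9.00, lies between the other WT arrays and the KO arrays.

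In KO ear skin 5 of the gene lists had more members higher than other genes did: ligands of the epidermal growth factor receptor family, small proline-rich proteins, barrier lipid genes, immediate early genes and antimicrobial proteins. Of these 5, 2 passed against the members of the other lists, 4 after quantile normalization and after median centring, and 0 without moderation or without KO replicate 2, WT replicate 2 or WT replicate 3. The largest rise with all KO arrays above all WT arrays was that of S100a9, a calcium-binding protein of neutrophils and stressed keratinocytes, at 37.3-fold (log2 difference 5.22, SE 1.04, limma adjusted p = 0.0149); the difference was 6.32 without WT replicate 1 and 4.44 without WT replicate 2. It was followed by the small proline-rich pseudogene Sprr2j-ps at 4.34 log2 units, the mast cell tryptase gene Tpsab1 at 4.30, Sprr2e at 3.64, and the cystatin-like protease inhibitor gene Stfa1, of cross-hybridisation class 3, at 3.57. The rest of the 10 largest rises were 2610528A11Rik at 3.38, the cystine transporter gene Slc7a11 at 3.19, Sprr2g at 2.99, the neutrophil surface marker gene Ly6g at 2.77 and Sprr2i at 2.77. Without WT replicate 1 the difference was 4.45 for Sprr2e, 4.55 for Stfa1, 4.33 for 2610528A11Rik and 3.91 for Slc7a11, and without WT replicate 2 it was 2.78 for 2610528A11Rik. The falls were smaller. The largest was that of Snhg9, a small nucleolar RNA host gene, with a log2 difference of -3.19 (SE 0.12, limma adjusted p = 1.49e-05), from 8.14 ± 0.20 in WT to 4.95 ± 0.08 in KO (SD, n = 4 each). Snhg9 and Tpsab1 lie on chromosome 17, as Cdsn does. For them, alleles carried with the floxed gene and an effect of Cdsn loss cannot be told apart. After Cdsn came Tmem213 at -1.90, the predicted gene Gm22575 at -1.88, the predicted gene Gm22019 at -1.81, the olfactory receptor gene Olfr317 at -1.72, the myosin kinase gene Mylk4 at -1.70, the predicted gene Gm22302 at -1.68, Mrgpra9 at -1.61 and the zinc finger gene Zfp982 at -1.48. Gm22575, Gm22019 and Gm22302 were of cross-hybridisation class 3. Tmem213, Gm22575, Gm22019, Olfr317, Gm22302, Mrgpra9 and Zfp982 had a mean below the median of 5.50. They lay at percentiles 19.2 to 46.8 of mean value over all probe sets. Snhg9, Cdsn and Mylk4 lay above the median. Of the 10 largest rises, Sprr2i, Ly6g and Sprr2g lay below it, at percentiles 29.6 to 46.7. No detection call was used, so whether the genes of low level are expressed in ear skin was not analysed.

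In all, 4428 of 33793 probe sets were called by limma at adjusted p under 0.05, 3350 higher and 1078 lower in KO, and 2644 of them changed at least 1.5-fold. The direction of the calls depended on scaling, because the median log2 difference over all probe sets was 0.094 in the deposited values and -0.021 after quantile normalization: the share of calls that were higher was 75.7% as deposited, 49.1% after quantile normalization (1689 higher and 1751 lower) and 53.2% after median centring (1819 higher and 1598 lower). Among the 3022 named genes, the KO and WT values did not overlap for 2867, or 94.9%, where chance gives 2.86% for unselected genes; these were selected as called. Leaving out single arrays lowered the number of calls, to 2161 without KO replicate 2, 2281 without WT replicate 2, 2335 without WT replicate 3, 2751 without KO replicate 1 and 2883 without WT replicate 4. Of the 87 genes named by rule, 34 were called with each of the 8 arrays left out, among them Cdsn, Snhg9, Tpsab1, S100a9, Sprr2e, Sprr2g and Sprr2j-ps. With dim probe sets left out, 40 of the 66 of these genes still tested lost their call, among them Krt1 (adjusted p = 0.0540), Stfa3 (0.0607), Sprr2a2 (0.0659), S100a8 (0.0768) and Epgn (0.0786). The call was lost for 2610528A11Rik in 7 of the 8 fits with an array left out, for Ly6g in 6, for Stfa1 and Slc7a11 in 5, for Mylk4 in 4 and for Sprr2i in 3, with adjusted p of at most 0.112.

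**Figure D2:**
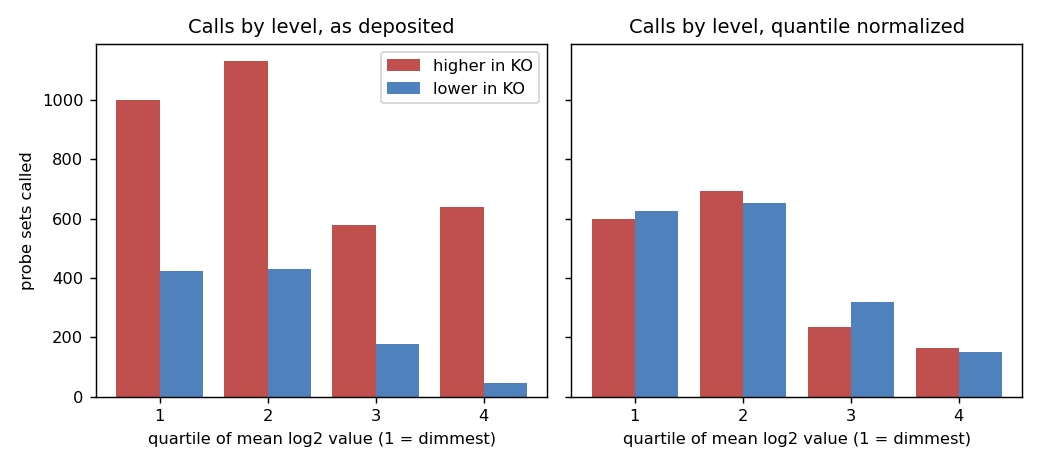
Number of probe sets called higher (red) or lower (blue) in KO in each quartile of mean log2 value over the 8 arrays, with the deposited values on the left and quantile-normalized values on the right. As deposited, 999 and 1132 of the higher calls lie in the dimmest quartiles, 1 and 2, and 640 in the brightest, where 45 were lower.

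Of the 15 small proline-rich protein genes, precursors of the cornified envelope, 8 were higher and 0 lower, with rises of 0.97 to 4.07 log2 units; the largest were Sprr2a2 (4.07, cross-hybridisation class 3), Sprr2e (3.64), Sprr2d (3.49) and Sprr2g (2.99). The share among the protein-coding members, 7 of 14, exceeded that of other genes (one-sided Fisher's exact test, adjusted p = 0.000331, and 0.0346 against the members of the other lists). Of 27 genes for the lipids of the skin barrier, 9 were higher and 0 lower (adjusted p = 0.000494, and 0.10 against the other lists), with rises of 0.53 to 1.13; they included the ceramide synthase gene Cers3 (1.13, SE 0.17), the glucosylceramide synthase gene Ugcg (1.04, SE 0.20), the lipoxygenase gene Alox12b (0.85) and the cholesterol sulfotransferase gene Sult2b1 (0.83). The call depended on scaling: the list's adjusted p was 1 after quantile normalization, with 2 members left, and 0.440 after median centring. Both lists moved with WT replicate 1, which lay towards KO: without it the median rise of the listed members was 3.63 in place of 2.98 for the small proline-rich genes and 0.77 in place of 0.70 for the lipid genes. Without WT replicate 1 the difference was 5.32 for Sprr2a2 and 4.38 for Sprr2d, and without WT replicate 3 it was 2.81 for Sprr2d. Leaving out other arrays ended the calls. For the small proline-rich genes the adjusted p was 0.912 without KO replicate 1, 1 without KO replicate 2, 0.0805 without KO replicate 3, and 1 without WT replicate 2, 3 or 4; it was also 1 with dim probe sets left out and 1 without moderation. For the lipid genes it was 1 without KO replicate 2, 0.130 without KO replicate 3, 0.893 without WT replicate 2, 0.0866 without WT replicate 3, 0.0781 without WT replicate 4 and 0.178 without moderation. Of the single genes, Sprr2e, Sprr2g, Cers3 and Ugcg were called with each array left out; Alox12b lost the call in 3 of the 8 fits, Sprr2d in 6 and Sprr2a2 and Sult2b1 in 7, with adjusted p of at most 0.112.

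Other epidermal lists had members that rose without the list passing the test on all 8 arrays as deposited. Of 30 epidermal differentiation genes, 6 were higher and 0 lower (adjusted p = 0.0918), led by the filaggrin-like repetin gene Rptn (3.33), the protease gene Casp14 (1.95), the suprabasal keratin gene Krt1 (1.88) and the transglutaminase gene Tgm1 (1.11). Of 21 kallikreins and inhibitors, which govern the cleavage of corneodesmosomes, 5 were higher (adjusted p = 0.0905), with Klk13 at 3.72, Klk9 at 1.93, Klk8 at 1.72 and Klk11 at 1.02. The differentiation and kallikrein lists each passed without WT replicate 1 and without KO replicate 4. Of 15 stress keratin and related genes, 4 were higher (adjusted p = 0.10), namely Stfa3 (5.09), Stfa1 (3.57), Stfa2 (2.07) and the AP-1 gene Fosl1 (1.81). The keratin genes of this list, Krt6a, Krt6b, Krt16 and Krt17, were not in the table. This list passed after quantile normalization and after median centring, through those related genes and not through keratins. Of 21 late cornified envelope genes, 2 were higher, Lce3f at 3.82 and Lce3e at 3.57. Of 15 desmosome genes, 2 were higher, the cadherin genes Dsg3 (0.77) and Dsc1 (0.60), and of 15 basal keratinocyte genes the integrin gene Itga3 was higher (0.73). Without WT replicate 1 the difference was 6.50 for Stfa3, 4.81 for Lce3f, 4.70 for Klk13, 4.55 for Stfa1, 4.49 for Lce3e and 4.29 for Rptn, and without WT replicate 3 it was 4.40 for Stfa3. In WT replicate 1, Krt1 read 12.56 against 10.30 to 10.91 in the other WT arrays and 12.63 to 13.56 in KO. Of these genes, Stfa2 was called with each array left out, and the others lost their call in 4 to 6 of the 8 fits, with adjusted p of at most 0.115. Stfa2 was of low level, at percentile 25.6 of mean value over all probe sets. Lce3f, Lce3e, Rptn, Casp14, Klk8, Klk11, Dsg3 and Itga3 were not called after quantile normalization, with limma adjusted p of 0.0566 to 0.0697.

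Ligands of the epidermal growth factor receptor family formed the list with the strongest test. Of its 8 members, 6 were higher in KO and 0 lower (one-sided Fisher's exact test, adjusted p = 0.000114, and 0.00800 against the members of the other lists). Epgn rose by 3.11 log2 units (SE 0.86), Areg by 2.23 (SE 0.48), Hbegf by 1.99 (SE 0.38) and Ereg by 1.21 (SE 0.20), with limma adjusted p between 0.00789 and 0.0448; Nrg1 and Tgfa were also higher. Of 16 immediate early genes, which respond within minutes to growth factors and stress, 7 were higher and 0 lower (adjusted p = 0.000494, and 0.0611 against the other lists), among them Nr4a1 (1.38, SE 0.28), Ier3 (1.34, SE 0.33), Junb (1.32, SE 0.25) and Dusp1 (1.18, SE 0.25). Without WT replicate 1 the rise of Epgn was 4.08, and the median rise was 1.76 over the ligands and 1.09 in place of 1.18 over the immediate early genes. The ligand list missed the threshold without KO replicate 2 (adjusted p = 0.0653), WT replicate 2 (0.0690) or WT replicate 3 (0.0866). The immediate early list missed it without KO replicate 1 (0.0714), KO replicate 2 (0.0653), WT replicate 2 (0.0690) or WT replicate 3 (0.435). Without moderation the adjusted p was 1 for both lists. Hbegf, Ereg, Nr4a1 and Junb were called with each array left out, while Epgn lost its call in 6 of the 8 fits, Ier3 in 5, Areg in 3 and Dusp1 in 1, with adjusted p of at most 0.114.

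Of 19 antimicrobial protein genes, 7 were higher in KO and 0 lower (one-sided Fisher's exact test, adjusted p = 0.00147, and 0.115 against the other lists), by 0.85 to 5.22 log2 units. They were led by S100a9 (5.22), its partner S100a8 (4.02), the beta-defensin gene Defb4 (3.57) and the iron-sequestering lipocalin gene Lcn2 (2.33, SE 0.44). Of the 7, S100a9, S100a8 and Camp are also on the list of neutrophil markers, on which Ly6g (2.77) and Cxcr2 (2.53) were higher too. Lcn2 and S100a9 were called with each array left out. S100a8 lost its call in 7 of the 8 fits and Defb4 in 5, with adjusted p of at most 0.111. Both also missed the threshold after quantile normalization (limma adjusted p = 0.0528 and 0.0598) and after median centring (0.0518 and 0.0531). WT replicate 1 moved with this group: S100a8 read 11.57 in it, against 5.65 to 8.03 in the other WT arrays and 11.31 to 12.47 in KO, and without this array the median rise of the 7 members was 2.55 in place of 2.33. The difference was 6.32 for S100a9, 5.25 for S100a8 and 4.49 for Defb4 without WT replicate 1, and 4.44 for S100a9 and 3.27 for S100a8 without WT replicate 2. The list missed the threshold without KO replicate 1 (adjusted p = 0.535), KO replicate 2 (0.575), WT replicate 2 (0.0808) or WT replicate 3 (0.522), with dim probe sets left out (0.649) and without moderation (1).

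Among cytokine lists, 3 of 16 IL-1 family genes were higher, Il1f6, which encodes IL-36 alpha, at 2.65, Il1a at 1.92 and the IL-33 receptor gene Il1rl1 at 1.67. Of 22 type 17 genes, 4 were higher, Il24 at 2.62, Nfkbiz at 1.46, Il17f at 1.17 and Zc3h12a at 0.94, and of 22 type 2 genes Alox15 was higher at 1.15. Adjusted p was 0.465 for the IL-1 family and 0.341 for type 17, so neither list passed. Of 27 interferon response genes, Oas3 (0.80) and Oasl1 (0.76) were higher and Ifit2 was lower (-0.73). Among tissue remodelling genes, Adam8 (2.17) and Mmp1b (1.21) were higher, and of 17 NRF2 targets Slc7a11 (3.19) and Txnrd1 (0.54) were higher. Mmp1b was of low level, with means of 2.35 in WT and 3.56 in KO, at percentile 11.4 of all probe sets. Nfkbiz, Il17f, Zc3h12a and Alox15 were called with each array left out, and the others lost the call in 1 to 6 of the 8 fits, with adjusted p of at most 0.0953. The difference for Il24 was 3.20 without KO replicate 3. Without WT replicate 1 the median rise was 2.21 in place of 1.92 for the 3 IL-1 family members and 1.35 in place of 1.31 for the 4 type 17 members.

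Single immune cell markers were higher in KO, and none of their lists passed the test. Of 19 neutrophil markers, 5 were higher (adjusted p = 0.0670), S100a9, S100a8, Ly6g (2.77), the chemokine receptor gene Cxcr2 (2.53) and Camp. Of 12 mast cell markers, 3 were higher: Tpsab1 (4.30, SE 0.31), the serotonin synthesis gene Tph1 (1.81) and the tryptase gene Tpsb2 (1.52). The other 9 were not in the table. Of the 11 protein-coding members, 2 were higher (one-sided Fisher's exact test, adjusted p = 0.790). Tpsab1 read 4.91 to 5.17 in all WT arrays and 8.56 to 10.05 in KO, and did not follow WT replicate 1. Both tryptase genes lie on chromosome 17, as Cdsn does, so alleles carried with the floxed gene may contribute to their rise. Of 19 T cell markers, Icos (1.43) and Foxp3 (1.17) were higher, and of 12 eosinophil and basophil markers Alox15 was higher. No member of the macrophage, dendritic and Langerhans cell or B cell lists was in the table. Icos and Tpsab1 were called with each array left out; Cxcr2 and Tph1 lost the call in 4 of the 8 fits, Tpsb2 in 5, Ly6g and Foxp3 in 6, with adjusted p of at most 0.112.

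Lists for other cells of the ear had few members in the table. Of 29 hair follicle genes, 4 were higher, among them the keratin gene Krt26 (0.97), Gprc5d (0.70) and Foxn1 (0.50). Single members were higher in the lists for proliferation (Rrm2, 1.07), cartilage (Prg4, 1.62), fibroblasts and matrix (Thbs2, 1.11), endothelium (Cdh5, 0.60), clock (Bhlhe40, 0.71), erythroid (Hbb-bt, 0.63) and sex-linked genes (Tsix, 0.79). Single members were lower in the lists for sebaceous gland (Gal, -0.80) and skeletal muscle (Tnnc2, -0.71). Krt26, Gprc5d, Thbs2, Bhlhe40, Hbb-bt, Tsix and Gal were called with each array left out. The others lost the call in 4 to 7 of the 8 fits, with adjusted p of at most 0.122. Krt26, Hbb-bt, Tsix and Gprc5d were of low level, at percentiles 20.5, 23.4, 24.9 and 26.6 of mean value over all probe sets. No detection call was used, so whether these genes are expressed in the tissue was not analysed. No member of the cholesterol synthesis, tight junction or adipocyte lists was in the table. Of the 37 lists, 5 passed as higher and 0 as lower by Fisher's exact test, with 10 and 0 tests at an unadjusted p under 0.05, and 2 lists, the receptor ligands and the small proline-rich genes, passed against the other lists.

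**Figure D3:**
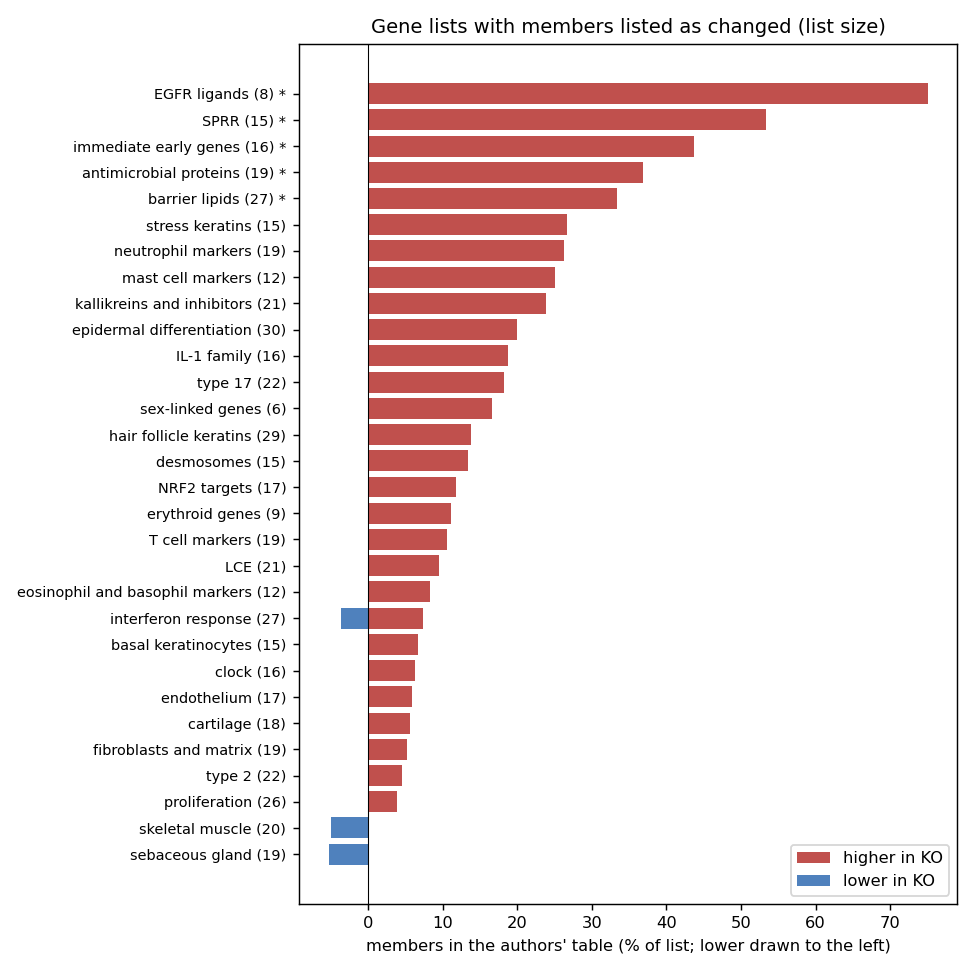
Share of each gene list found in the authors' deposited table as higher (red, to the right) or lower (blue, to the left) in KO, as a percentage of the list's genes in the reference; the number in brackets is the list size, an asterisk marks the 5 lists that passed the test, and lists with no member in the table, and 2 further lists, are not drawn. The receptor ligands have 6 of 8 members higher, and 2 lists, each with 1 member, have lower members alone.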

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

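Of the tests in this part, the search for calls near Cdsn and the count of other splits of the arrays were set before the values were seen; the other tests of explanations were chosen after the patterns were seen.

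In 176 groups of 4 arrays examined, the values of 87 genes and the array medians in each genotype, 10 held an array whose gap to its nearest neighbour was above Dixon's 95% critical value as a share of the group's range, and chance gives about 1 in 20. Of the 10, 5 were WT replicate 1 as the highest WT array: Sprr2e (0.956), Stfa1 (0.908), Lce3e (0.851), Epgn (0.845) and Klk8 (0.836). WT replicate 4 was apart as the highest for Gal (0.910) and Gm22575 (0.842). KO replicate 3 was the lowest for Alox15 (0.924), KO replicate 4 the highest for Gm22575 (0.892) and KO replicate 2 the highest for Mrgpra9 (0.874).

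WT replicate 1 lay between the groups for many genes: on a scale with the other WT arrays at 0 and KO at 1, in a fit without it, its median place was 0.412 for 839 higher probe sets of above-median level (bright). A wrong label is argued against by Cdsn, at 12.05 in this array and at most 10.31 in KO. RNA of a KO sample mixed in is argued against by Tpsab1: the share of 28.9% estimated from the other 9 largest rises would bring it to 7.76 log2 units, 2.58 above its value of 5.17, and even the lowest single-gene share, 9.90%, would bring it to 6.58. A difference in scale is argued against by quantile normalization, after which the place was 0.597. A response of this animal's skin to the treatment or to something else remains a hypothesis that no label tests.

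Calls were concentrated in probe sets of below-median level (dim), which held 67.4% of them. A difference in scale between the groups as the whole cause is argued against by quantile normalization, after which dim probe sets held 74.8%. Alleles carried with the floxed gene on chromosome 17 are argued against as the main cause. Of the dim probe sets of the table, 4.28% lie there. A smaller contribution stays open. Of protein-coding genes, 5.10% on chromosome 17 were dim genes of the table, against 4.47% elsewhere (one-sided Fisher's exact test, adjusted p = 0.314). Whether dim probe sets follow the same response as bright ones cannot be told apart from these arrays: in 2 of the 3 arrays that lie between the groups the dim median lay nearer the array's own group than the middle 50% of the bright places did, and in the third, KO replicate 3 for probe sets higher in KO and WT replicate 1 for those lower, it lay within it. A batch of labelling or scanning that follows genotype stays open, as the labels give none.

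Alleles of another strain can travel with a targeted gene, and genes near Cdsn were examined for that. Within 5 Mb of Cdsn 31 of 291 protein-coding genes were in the table (10.7%), against 1725 of 21608 elsewhere (7.98%), so the planned test left the question open (one-sided Fisher's exact test, p = 0.0641). Among 12 such tests, bright genes lower in KO were more frequent within 20 Mb, 13 of 730 against 107 of 21169 (adjusted p = 0.00224). Within 5 Mb they were 3 of 291 against 117 of 21608 (adjusted p = 0.321), which did not pass. Bright genes higher in KO and dim genes passed in no region tested. On chromosome 17 the median place of bright lower probe sets in WT replicate 1 was 0.033 for 11, against 0.247 for 90 on other chromosomes (permutation p = 0.0391). A difference bound to the genotype of the region predicts such a place. The permutation treats probe sets of 1 mouse as independent, so it is no test across mice. More mast cells as the whole cause of the rise of Tpsab1, also on chromosome 17, is argued against by its excess of 2.78 log2 units (SE 0.21) over Tpsb2. Passenger alleles and an effect of Cdsn loss on these genes, and on Snhg9 of the same chromosome, cannot be told apart, since every KO mouse carries the floxed region.

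The number of calls was compared with other splits of the 8 arrays into 4 and 4. Of 35 splits, 1, the real one, gave as many as 4428 calls, and the highest of the others gave 25. A share of 1 in 35 is the smallest that these arrays allow. It argues against chance in the assignment of arrays without excluding it. A batch that follows genotype could give a like result.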

How the results depend on the processing

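The test of gene lists and its second background were chosen after seeing the data; the other settings were planned. Cdsn kept its direction and call under all settings run, with log2 differences of -2.60 to -2.13 and adjusted p of 0.00121 to 0.0144. Of the 87 named genes, 21 lost their call after quantile normalization, 16 after median centring, 58 without moderation, 51 without KO replicate 2 and 40, of 66 tested, with dim probe sets left out.

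With quantile normalization 1689 probe sets were higher and 1751 lower, and with median centring 1819 were higher, because the groups differ in scale. With dim probe sets left out, 718 of the 1442 calls above that level were made, 595 higher and 123 lower, 355 of them by at least 1.5-fold, and 3 lists passed, without the small proline-rich and antimicrobial lists. Without moderation 1651 changed by at least 1.5-fold and 0 lists passed. For both settings the cause was not tested. At adjusted p under 0.01, 979 were called, 716 higher and 263 lower; at 0.1, 7521, of which 5619 higher and 1902 lower. A minimum fold of 2 left 552. Against the members of other lists 2 lists passed.

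With 1 array left out, and so fewer samples, calls ranged from 2161 to 3504, higher calls from 1574 to 2670, lower calls from 582 to 837, calls of at least 1.5-fold from 1761 to 2625 and lists from 0 to 7. The 0 came without KO replicate 2, WT replicate 2 or WT replicate 3.

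With the replicate number as a block, 5150 probe sets were called, 3917 higher and 1233 lower. The numbers are not known to pair mice: deviations of same-numbered arrays correlated at 0.548, -0.062, 0.276 and 0.304, and KO replicate 2 and WT replicate 2 each correlated best with another number. Not run were the mean of a gene's probe sets, camera with an estimated correlation and fry, which need names for all probe sets, and values per array of the second table, which gives group means. Signal over background limits probe sets of low level, and no detection call was used here.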

Other observations

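The groups of this paragraph and the next were put together after the values were seen, and the values carry no test of the group. Of their genes, Nfkbiz, Zc3h12a, Mylk4 and Tnnc2 were named by the rule, and the others were chosen after their values were seen. Several of all these genes lie close to the threshold of adjusted p under 0.05 in limma. Genes regulated by oxygen were among the higher ones: the hypoxia factor gene Hif1a (log2 difference 1.09), the vascular growth factor gene Vegfa (0.89), the prolyl hydroxylase gene Egln3 (1.06), the glycolytic gene Pgk1 (0.95), the lactate transporter gene Slc16a3 (1.38) and Fam162a (1.61). Their adjusted p ran from 0.0199 to 0.0485, 3 of the 6 were called after quantile normalization, and 0 were called with each array left out, where adjusted p reached 0.116. Genes that restrain or modify NF-kB signalling were also higher, Tnfaip3 (1.06), Bcl3 (1.22), Nfkbid (1.78), Nfkbiz (1.46) and Zc3h12a (0.94), with adjusted p from 0.00679 to 0.0396. Of these 5, 3 were called after quantile normalization. Nfkbiz and Zc3h12a were called with each array left out, and the others reached 0.103. Without WT replicate 1, the difference was 0.80 for Vegfa and 1.48 for Bcl3.

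Several genes known from striated muscle were lower in KO. They were Mylk4 (-1.70), the myostatin gene Mstn (-1.29), the cytochrome oxidase subunit genes Cox7a1 (-1.15) and Cox8b (-0.81), Smpx (-0.97), Hjv (-0.87), Pgam2 (-0.78), Apobec2 (-0.77), Tnnc2 (-0.71), Tpm1 (-0.67) and Asb5 (-0.61). Their adjusted p ran from 0.00634 to 0.0488, and Cox7a1, Smpx and Tpm1 were called with each array left out, while the other 8 lost the call in at least 1 fit. After quantile normalization all 11 were called. The list of 20 skeletal muscle genes fixed beforehand had 1 member in the table, Tnnc2, and did not pass as lower by Fisher's exact test. Its other members have no named values here, so a smaller change of that list as a group could not be tested.

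Some families defined by their symbols differed from the other named genes in the balance of directions. Of 27 numbered zinc finger genes in the table, 9 were higher and 18 lower, a lower share of rises than the other named genes had (Fisher's exact test, adjusted p = 9.28e-05 over 13 families). The test treats related genes as independent. Among the lower ones, Zfp960, Zfp758 and Zfp959 lie on chromosome 17, where alleles carried with the floxed gene cannot be told apart from an effect of Cdsn loss. In 15 further tests, added after seeing the data, 28.0% of the zinc finger genes still called after quantile normalization were higher, against 65.7% of the other named genes still called (adjusted p = 0.000642), and among dim genes 28.6% against 71.4% (adjusted p = 0.00252). Predicted genes with Gm symbols had 563 higher and 249 lower, 69.3% against 76.5% of other named genes (adjusted p = 0.000586), at a median level of 4.03; among dim genes the shares were 68.4% and 72.5% (adjusted p = 0.0539), so that difference did not pass at like levels. MicroRNA genes had 28 higher and 21 lower (adjusted p = 0.0326), and among dim genes 52.4% were higher against 71.5% of the others (adjusted p = 0.0120). Olfactory receptor genes had 106 higher and 38 lower, and vomeronasal receptor genes 36 and 9. Neither family passed (Fisher's exact test, adjusted p = 0.909 and 0.770). Their median percentiles of mean value were low, 16.4 and 18.9, and whether they are expressed in ear skin was not analysed. Of 130 probe sets on the Y chromosome in the table, 121 were higher, 125 were of cross-hybridisation class 3 and their median level was 4.38; none of the 4 single-copy Y genes of the sex-linked list was in the table.

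Annotation terms in the authors' deposited table gave no further group. Of 190 terms tested for an uneven balance of higher and lower genes, 0 passed by Fisher's exact test after adjustment and 17 had an unadjusted p under 0.05; keratinization, with 13 genes higher and 0 lower, had an adjusted p of 0.550.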
